A study of Sus scrofa with 14 samples.

How the data were processed

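Total RNA from endometrium of 14 gilts was labelled and hybridised to an Affymetrix porcine array, 1 array per gilt, per the labels. The deposited values are signal intensities on a linear scale, 1 per probe set and array, as the authors made them from the scanned images; the labels do not name the software or its scaling target. The values show that every array has the same 2% trimmed mean of 500.1, so the intensities had been scaled between arrays before deposition. Median signals were 178 to 218 and the highest signals 23866 to 49517. Arrays give no counts, and their number limits the precision.

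The table held 24123 probe sets. The 188 control probe sets were left out, and values were analysed as log2(signal + 16). The dimmest 30% of probe sets by mean log2 value over the 14 arrays (under 6.35) were left out, which left 16754 to test. Gene symbols came from the table of probe genes: 10099 probe sets had 1 symbol, 198 had several and were not named, and 13826 had none. Gene identifiers matched the reference table for 9989 of the named probe sets, and 110 had no match. Among the tested probe sets 7965 had 1 symbol, for 5785 genes.

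All 4 groups entered 1 fit in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a trend on mean level), with Benjamini-Hochberg adjustment over the 16754 probe sets and a threshold of 0.05. The comparisons were estrogen against control at day 13, at day 15 and averaged over both days, day 15 against day 13 in control and in estrogen gilts, and the difference of the estrogen effect between the days. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for exact permutation tests and figures.

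A total of 25 gene lists were written before the data were examined, as were the comparisons, the test, the alternatives and the rule for naming genes. Of these, 16 were on processes: gland secretions, estrogen and progesterone receptor targets, prostaglandins, integrins and mucins, interferon response and antigen presentation, interleukin 1 and cytokines, collagens and matrix, cell cycle, WNT and uterine transcription factors, cholesterol and steroid metabolism, nutrient transport, complement and coagulation, endoplasmic reticulum chaperones, hypoxia and glycolysis, oxidative phosphorylation, and apoptosis. The remaining 9 were cell type markers: epithelium, ciliated epithelium, stromal fibroblast, smooth muscle, endothelium, macrophage, lymphocyte, red blood cell and trophoblast. The 24 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Each gene was represented by its probe set with the highest mean. Members were also adjusted over the list alone. Some genes belong to more than 1 list, so the list results are not independent of each other. Fry tests a list by itself, and its p values are given unadjusted.

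The genes named were, per comparison, the 10 with the lowest p among named genes, or, where genes passed the threshold, the 12 with the largest changes each way among those whose compared groups did not overlap; 1 gene that this rule names is not reported here, for a reason unrelated to its values, and stays in all counts. Genes named as members of a list, and those used to describe the 3 arrays that stand apart, were chosen after their values were seen. The method was tested on simulated data with the group sizes of this series. Of probe sets given a log2 change of 1, 2 or 3 between the days in estrogen gilts, it called 40%, 80% and 98.3%, with 5 false calls. A shifted list was called in 20 of 20 runs and unshifted lists in 1 of 460 tests. The simulated genes were drawn independently, so these runs do not show how often lists of correlated genes are called in error.

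The alternatives were no filter or the dimmest 50% left out, quantile normalization, median centring, pseudocounts of 1 and 64, a fit of only the groups compared, array weights, no trend, the replicate number as a term, 1 probe set per gene, every probe set of a list's genes, and each array left out in turn. Leaving out the 3 arrays whose median correlation lay more than 3 median absolute deviations under the median of all arrays was added after the data were seen, as was a fit of the day effect pooled over treatments. A fit with RNA quality as a covariate was added too, with and without these 3 arrays. The covariate was the mean of the standardised 3' minus 5' log2 differences of GAPDH, actin and EF1A.

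Whether the replicate numbers pair the samples was checked from the correlation of the arrays' deviations from their group means. In the comparison of estrogen with control at day 13, all 4 same-numbered pairs had a correlation over 0.1 (0.132 to 0.283). The 12 other pairs had -0.259 to 0.1, and all 8 arrays correlated best with their own number. These numbers were therefore treated as possible pairs. The values alone gave this, since the labels name no shared source, and they do not establish a pairing. Deviations from a group mean cancel within the group, so the correlations are not independent of each other. Over all comparisons the median correlation of same-numbered pairs was -0.003, against 0.018 for other pairs. In each of the other comparisons between groups 1 of 3 pairs had a correlation over 0.1, and the numbers were not taken to pair the samples. A fit of the day 13 groups with the replicate number as a block was added after the data were seen, and called 0 probe sets in limma, with 800 at an unadjusted p under 0.05.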

Results

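Gene expression was measured in the endometrium, the lining of the uterus, of 14 crossbred gilts (young female pigs) on a porcine oligonucleotide array with 1 biotin-labelled RNA sample per array. At the onset of their second estrus, and again 24 hours later, gilts received estrogen or corn oil, and tissue was taken on day 13 or day 15 of pseudopregnancy. The submitters describe these days as covering the time at which conceptuses attach to the uterus in the pig, and the estrogen gilts as having had an endocrine disruption of pseudopregnancy. There were 4 control and 4 estrogen gilts at day 13, and 3 control and 3 estrogen gilts at day 15, labelled as biological replicates. Of 23935 biological probe sets, 16754 were bright enough to test, and 5785 genes were named among them. Median signals lay between 178 and 218 per array. The number of arrays limits the precision of every value.

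Of the arrays, 3 stood apart from the other 11: control day 13 replicate 1, control day 15 replicate 3 and estrogen day 15 replicate 2. Their median correlations with the remaining arrays were 0.860, 0.873 and 0.885, against 0.927 to 0.952 for the others, and the first principal component, with 40.6% of the variance, held them away from the rest. Genes picked after these arrays had been seen show the size of the difference. PLAT, tissue plasminogen activator, had log2 values of 13.68, 13.37 and 12.76 on the 3 arrays and 8.84 to 9.83 on the others. MMP7, an epithelial matrix metalloproteinase, had 12.31, 12.47 and 14.20 against 4.88 to 9.40. SLC39A2, a zinc transporter, had 10.33, 9.45 and 11.55 against 12.88 to 14.21. Because each of these arrays belongs to a different group, counts are given with all 14 arrays and, as an alternative chosen after the data were seen, without these 3.

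**Figure D1:**
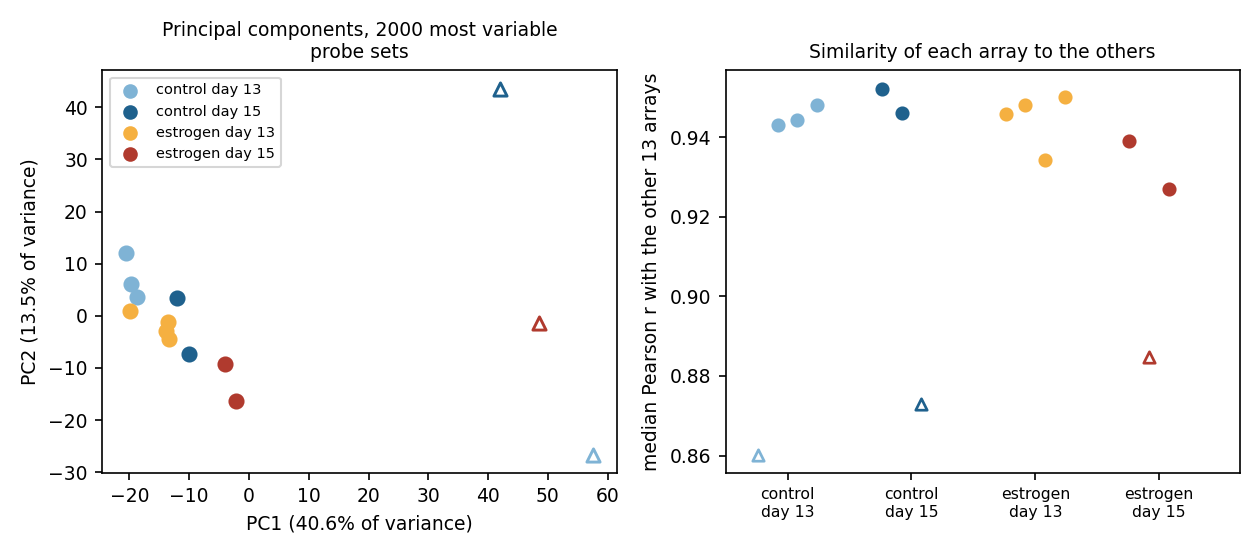
Left, first and second principal components of the 2000 most variable probe sets, 1 point per array, coloured by group. Right, the median Pearson correlation of each array with the other 13; open triangles mark the 3 arrays at 0.860, 0.873 and 0.885.

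The day comparison in control gilts asked how the endometrium of undisturbed pseudopregnancy differed between days 13 and 15. Macrophage genes, cholesterol synthesis genes and mitochondrial respiratory chain genes were higher at day 15 as lists. Each call was lost with an estimated correlation (adjusted p = 0.255, 0.182 and 0.276). MRC1, the mannose receptor of macrophages, had a log2 value of 7.20 ± 0.35 (SD, n = 4) at day 13 and 8.93 ± 0.73 (SD, n = 3) at day 15, a 3.33-fold difference. CD163, the macrophage scavenger receptor for haemoglobin, differed by 1.09 ± 0.24 (SE) on the log2 scale, or 2.13-fold, on its probe set with the highest signal and by 0.23 on another. HMGCS1, the first committed enzyme of the mevalonate pathway, went from 9.26 ± 0.27 to 10.53 ± 0.77 (SD, n = 4 and 3), and SQLE, the squalene epoxidase of sterol synthesis, from 9.51 ± 0.81 to 11.10 ± 0.59. None of these genes passed on its own over all probe sets: limma called 0 probe sets at day 15 against day 13 in control gilts, with 656 at an unadjusted p under 0.05 where 838 are expected by chance, and 0 without the 3 arrays that stand apart, with 857.

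As a group, the cholesterol and steroid metabolism genes rose in control gilts, with 17 of 21 measured members higher and a median log2 difference of 0.68 (camera adjusted p = 5.5e-06; adjusted p = 0.182 with an estimated correlation). On the list score, control day 13 replicate 1 was the lowest (-0.56) and control day 15 replicate 3 the highest (0.55) of the control arrays; without the 3 arrays that stand apart the median was 0.44 (adjusted p = 0.0226), and without the filter on dim probe sets it was 0.28. HMGCS1, CYP51, SQLE and MSMO1, all enzymes of sterol synthesis, passed when adjusted over the list alone, and 0 passed over all probe sets. Mitochondrial oxidative phosphorylation genes rose by a median of 0.28, with 23 of 27 higher (adjusted p = 5.16e-06; adjusted p = 0.276 with an estimated correlation); 0 members passed over all probe sets or adjusted over the list alone. NDUFA9 and NDUFS1, subunits of respiratory complex I, differed by 0.54 and 0.58, with unadjusted limma p of 0.017 and 0.028.

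Macrophage, dendritic cell and neutrophil genes rose in control gilts by a median of 0.51, with 9 of 11 higher (adjusted p = 9.1e-04; adjusted p = 0.255 with an estimated correlation, fry p = 0.0435, exact p of the list score 0.171). MRC1 and CD163 passed adjusted over the list alone. Without control day 15 replicate 2 that call ended (adjusted p = 0.0902), and without control day 13 replicate 1 or replicate 4 its median was 0.89 and 0.32. With the 3 arrays that stand apart left out its median was 1.09 with 8 members past the threshold adjusted over the list alone. The lymphocyte list, not called with all arrays, then rose by a median of 0.91 with 11 of 11 higher (adjusted p = 4.15e-06; adjusted p = 0.171 with an estimated correlation). Complement, coagulation and protease inhibition genes rose by a median of 0.36 (adjusted p = 0.00922; adjusted p = 0.276 with an estimated correlation), and C1S and C1R, the proteases that open the classical complement pathway, passed adjusted over the list alone. Leaving out control day 13 replicate 4, control day 15 replicate 2 or control day 15 replicate 3 ended this call (adjusted p = 0.114, 0.0902 and 0.0688), and without control day 13 replicate 2 the median was 0.23. Interferon response and antigen presentation genes rose by a median of 0.18, with 26 of 35 higher (adjusted p = 0.0318; adjusted p = 0.594 with an estimated correlation). Here too single arrays decided: the call ended without any 1 of 4 arrays, with adjusted p up to 0.463, and the median was 0.40, 0.11 and 0.34 without control day 13 replicate 1, control day 13 replicate 4 and control day 15 replicate 3, while without the 3 arrays that stand apart the median was 0.60 with 32 of 35 higher (adjusted p = 2.27e-09; adjusted p = 0.269 with an estimated correlation).

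Epithelial markers fell by a median log2 value of -0.26 between the days in control gilts, with 12 of 15 lower (adjusted p = 0.00539; adjusted p = 0.255 with an estimated correlation). MUC1, the mucin of the luminal surface, differed by -0.92 ± 0.33 (SE). This call ended without control day 15 replicate 1 or replicate 2 (adjusted p = 0.108 and 0.139). Without the 3 arrays that stand apart, epithelial markers (median -0.26) and integrins, mucins and junction genes (median -0.13, 18 of 25 lower) were called with an estimated correlation too, both at an adjusted p of 0.0382. The lists share members, MUC1 among them, so these calls are not separate results. They rest on 3 control arrays at day 13 and 2 at day 15. The 5 measured ciliated epithelium markers were all lower, at a median of -0.34 (adjusted p = 0.0492; adjusted p = 0.375 with an estimated correlation), a call that 16 of 28 alternatives ended; the median was -0.63 without control day 15 replicate 1. Among single genes named by the lowest p, none past the threshold, TMEM175, a lysosomal ion channel, differed by -1.89 ± 0.39 (SE), IGFBP5, a binding protein of insulin-like growth factors, by 1.01 ± 0.27 and OXTR, the oxytocin receptor, by 1.16 ± 0.32. SH3BGRL3, OXCT1 and HTRA1 differed by 0.64, 0.76 (0.13 on another probe set) and -1.30. Without control day 15 replicate 1 the mucosal chemokine CCL28, chosen after its values were seen, was the 1 probe set to pass, with a log2 fall of -2.47 (adjusted p = 0.015). OXTR was 8.01 on control day 15 replicate 3 and 6.79 and 7.05 on the remaining control arrays of that day.

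In estrogen gilts, interferon response, antigen presentation and macrophage genes were higher at day 15 than at day 13 as lists. These list calls were lost with an estimated correlation (adjusted p = 0.136 for each). MRC1 went from 7.14 ± 0.42 (SD, n = 4) to 9.43 ± 0.37 (SD, n = 3), a 4.89-fold difference. The class II antigen-presenting gene SLA-DQB1 went from 10.05 ± 0.32 to 11.96 ± 0.54, or 3.76-fold. CXCL9, a T-cell-attracting chemokine induced by interferon gamma, went from 6.17 ± 0.24 to 10.60 ± 1.77, with 9.15, 10.08 and 12.57 on the 3 arrays of day 15.

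**Figure D2:**
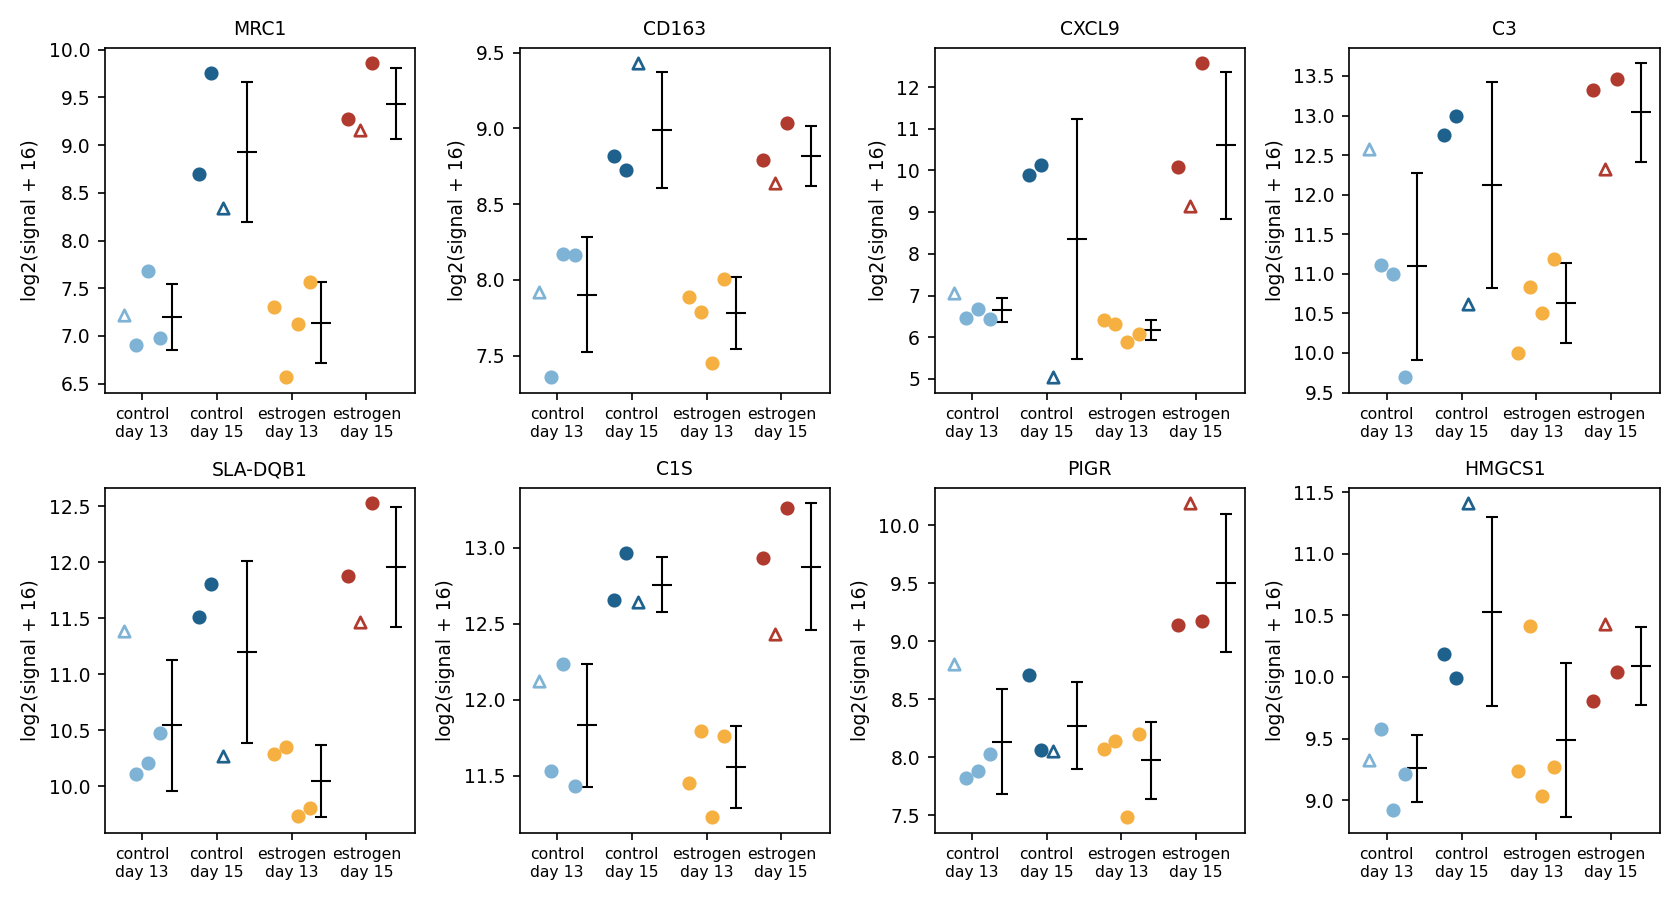
Log2(signal + 16) of 8 genes, 1 point per array and the mean ± SD beside each group; open triangles are the 3 arrays that stand apart. MRC1 means were 7.14 and 9.43 in estrogen gilts at days 13 and 15; the panels were chosen after the values were seen.

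Over all probe sets and all 14 arrays, limma called 0 probe sets between the days in estrogen gilts, with 1443 at an unadjusted p under 0.05 (799 higher, 644 lower), and the lowest adjusted p was 0.151, for MRC1. The count differed between settings. Without the 3 arrays that stand apart 221 probe sets passed, 130 higher and 91 lower; down-weighting arrays by their quality called 168, and fitting only the estrogen gilts called 99. In these 3 settings 58 probe sets passed each time, in the same direction. In the fit of all arrays all 221 had the same direction and 206 an unadjusted p under 0.05 in limma. These fits share most of their arrays. The array weights were also lowest on the 3 arrays that stand apart (0.26 to 0.38, against 0.90 or more). Such agreement was therefore largely given in advance and is no independent support. Genes passing in each of the 3 settings included MRC1, AIF1, TYROBP and CD209 of myeloid cells, SLA-DQA1, SLA-DQB1, SLA-DMB, CD74 and CIITA of class II antigen presentation, C1S, C1R and C3 of complement, and the immunoproteasome subunits PSMB8 and PSMB10. Without control day 13 replicate 1 alone, 44 passed. Without control day 15 replicate 3, MRC1, CXCL9 and an unnamed probe set passed (adjusted p = 0.0316 each), and MRC1 alone passed without control day 15 replicate 2 (adjusted p = 0.028). CCL28 alone passed without control day 15 replicate 1, with a fall of -2.06 (adjusted p = 0.0273).

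RNA quality differed between these arrays. The 3' minus 5' difference of GAPDH was 1.86 to 2.20 on the day 13 arrays of estrogen gilts, 1.36 on estrogen day 15 replicate 2, and 2.56 and 2.85 on the others of day 15. These others also lay above the day 13 arrays for actin (2.34 and 1.82 against 1.07 to 1.72) and EF1A (0.24 and 0.18 against -0.10 to 0.03). In the fit that called 221, RNA quality and day therefore moved together in estrogen gilts. In a fit with RNA quality as a covariate, added after the results had been seen, limma called 0 probe sets between the days, with 2743 at an unadjusted p under 0.05, and 0 without the 3 arrays, with 1174. Of the 221 probe sets, 219 kept their direction in both; without the 3 arrays their median change was 1.38 with a median SE of 0.24 before and 1.43 with 0.52 after, so the calls ended through wider errors.

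Among the genes that passed without the 3 arrays, the largest rises were in CXCL9 (5.15 ± 0.49 SE, adjusted p = 0.00384), GP91-PHOX, the catalytic subunit of the phagocyte oxidase (3.41), the chemokine CXCL14 (3.30) and AMBN (3.13). GBP1, C3, PLEK, CIITA, UBD, MRC1, GMFG and AIF1 followed, with log2 rises of 2.85 to 2.17. Only 2 estrogen arrays of day 15 were left in this fit. The SE and adjusted p rest on a spread pooled over the groups, so they do not show how far these 2 arrays lay apart. The largest falls were in RLBP1, a retinaldehyde-binding protein (-2.54 ± 0.51 SE), LOC100157017 (-2.03), the ubiquitin ligase WWP2 (-1.85) and SLC34A2, a phosphate transporter (-1.48). IGFBP6, LPL, TMEM144, SLMAP, CYB5R1, PRELID3B and CPN1 fell by less, from -1.46 to -1.13. Another probe set of LPL differed by only -0.53 (adjusted p = 0.297). Other probe sets of GBP1 differed by 1.29 (adjusted p = 0.132) and 2.18. The day 13 means of CXCL9 (6.17), GP91-PHOX (5.86), AMBN (5.44), CIITA (5.56) and PLEK (5.58) and the day 15 mean of RLBP1 (5.39) lay under 6.35, the level below which probe sets were left out as dim. The size of these changes therefore depends on background and pseudocount. With all 14 arrays SLC34A2 differed by only -0.25, and its sign turned without estrogen day 15 replicate 1 (0.15) or replicate 3 (0.59). With all arrays, ZBP1, an interferon-induced nucleic acid sensor, differed by 1.43 ± 0.25 (SE), SRGN, the granule proteoglycan of leukocytes, by 1.64 ± 0.31, FAM107A by -1.21 ± 0.24 and SLMAP by -1.10 ± 0.22, none past the threshold.

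The interferon response and antigen presentation list rose between the days in estrogen gilts, with 32 of 35 members higher and a median log2 difference of 0.93 (camera adjusted p = 6.43e-15; adjusted p = 0.136 with an estimated correlation). Of its members 19 passed adjusted over the list alone and 0 over all probe sets. They included GBP1 (2.29 ± 0.47 SE), SLA-DQA1 (1.64), CD74 (1.56), the antiviral genes ISG15 (1.29) and RSAD2 (1.51), and the transcription factors IRF7 (1.47) and IRF1 (1.17). On the array list score, the 3 day 15 arrays had 0.49, 0.56 and 1.23 and the 4 day 13 arrays -0.35 to -0.12, which gave the smallest p an exact permutation test allows here, 0.0286 (2-sided; Benjamini-Hochberg p = 0.137 over 24 lists). The macrophage, dendritic cell and neutrophil list rose by a median of 0.95, with 10 of 11 higher (adjusted p = 2.61e-05; adjusted p = 0.136 with an estimated correlation). MRC1, CD163, TYROBP, AIF1 and C1QC passed adjusted over the list alone, while the neutrophil gene S100A9 differed by 0.18 ± 1.38 (SE). Lymphocyte and natural killer cell genes rose by a median of 0.55, with 10 of 11 higher (adjusted p = 0.00912; adjusted p = 0.581 with an estimated correlation), and IL2RG and PTPRC passed adjusted over the list alone. Without estrogen day 15 replicate 3 the lymphocyte call ended (adjusted p = 0.216). With RNA quality as a covariate the interferon and macrophage medians were 0.89 and 1.03 (adjusted p = 9.06e-06 and 0.0418), and the lymphocyte call ended (0.41, adjusted p = 0.512). Without the 3 arrays the lymphocyte median was 0.62 before the covariate (adjusted p = 0.0035) and 1.36 with it (adjusted p = 6.15e-04). The adjustment thus moved this list either way.

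**Figure D3:**
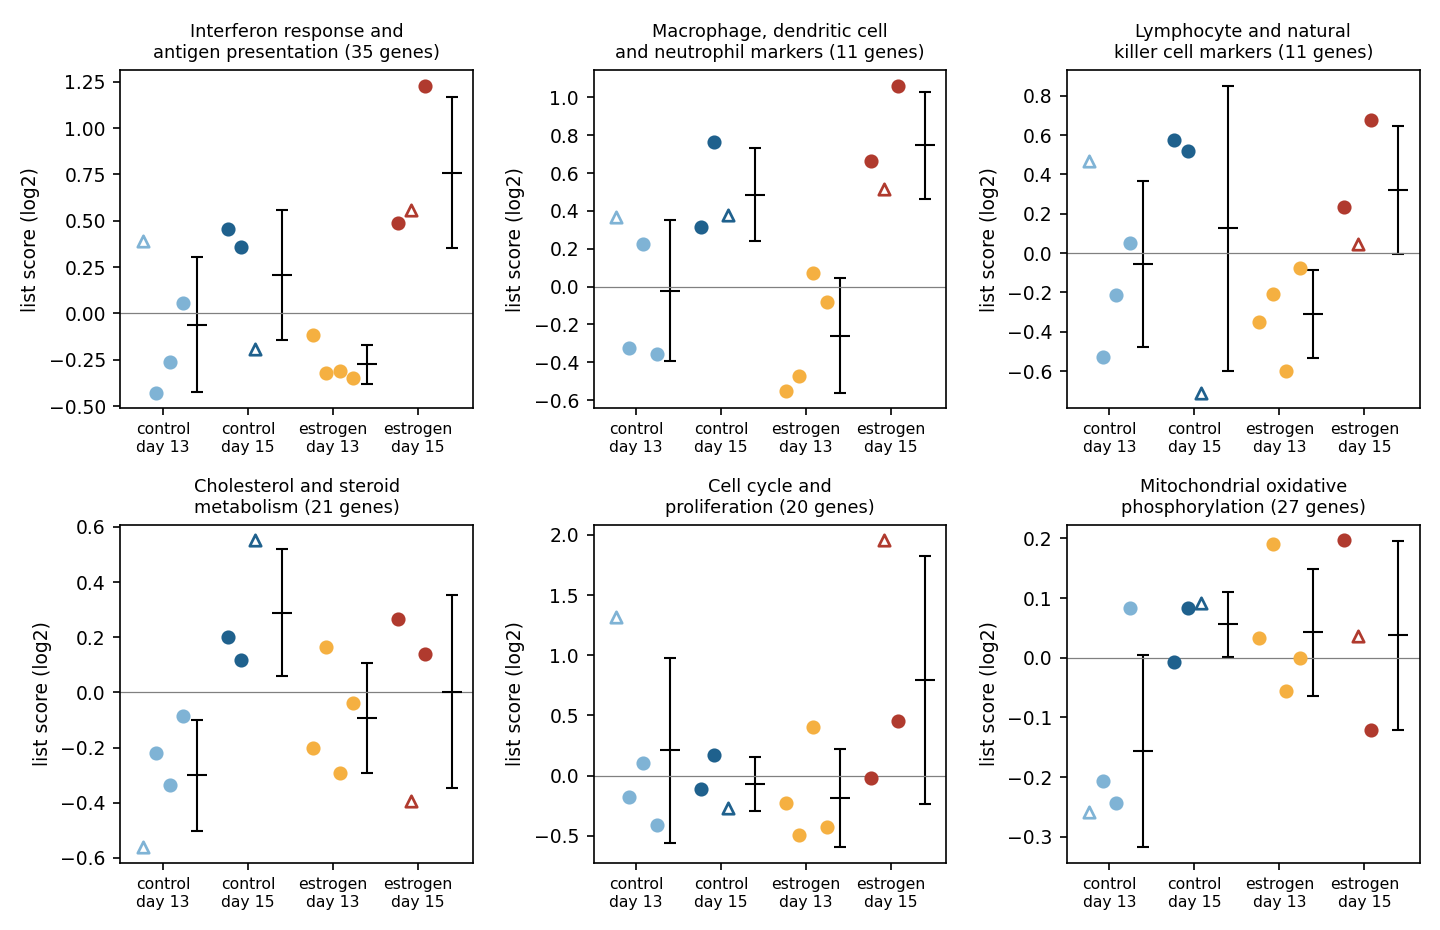
Scores of 6 gene lists, 1 point per array and the mean ± SD beside each group; a score is the mean over the list's genes of each log2 value minus that gene's median over the 14 arrays, and open triangles are the 3 arrays that stand apart. In estrogen gilts the interferon score was 0.49 to 1.23 at day 15 and -0.35 to -0.12 at day 13.

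Complement genes did not pass as a list in estrogen gilts (median 0.54, adjusted p = 0.0768), and were called without the 3 arrays (median 0.46, adjusted p = 0.00889; adjusted p = 0.539 with an estimated correlation). With all arrays 7 of 20 passed adjusted over the list alone: C1S (1.31 ± 0.25 SE), C1R, C3 (2.40 ± 0.63), C2, SERPING1 and CFB were higher and A2M (-1.97 ± 0.71) was lower. Cell cycle genes rose by a median of 0.94, with 19 of 20 higher and 0 past the threshold adjusted over the list alone (adjusted p = 2.2e-04; adjusted p = 0.581 with an estimated correlation). That call rested on estrogen day 15 replicate 2, whose score was 1.95 against -0.02 and 0.46 for the others of its group; without it the median was 0.40 (adjusted p = 0.465). The list of WNT, hedgehog, BMP and uterine transcription factors fell by a median of -0.26, with 16 of 21 lower (adjusted p = 0.00326; adjusted p = 0.0851 with an estimated correlation); IHH, the epithelial hedgehog ligand, differed by -0.58 ± 0.25 (SE). Testing every probe set of the list's genes ended this call (adjusted p = 0.0672). Estrogen and progesterone receptor targets fell by a median of -0.35, with 19 of 24 lower (adjusted p = 0.0242; adjusted p = 0.136 with an estimated correlation). C3, up by 2.40, was the 1 member past the threshold adjusted over the list alone, and the receptors ESR1 and PGR differed by -0.11 ± 0.34 and -0.12 ± 0.48 (SE). Without estrogen day 13 replicate 4 or estrogen day 15 replicate 2 the receptor target call ended (adjusted p = 0.06 and 0.241).

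The comparison of estrogen with control gilts at day 13 asked what the early treatment had left in the endometrium 13 days into pseudopregnancy. Respiratory chain genes were slightly higher after estrogen as a list, a call lost with an estimated correlation (adjusted p = 0.395). The proton pump subunit ATP6V0D2 was 10.15 ± 0.48 in estrogen and 8.37 ± 0.16 in control gilts (SD, n = 4 each), a 3.43-fold difference. FAM107A was 10.59 ± 0.20 against 9.37 ± 0.35, or 2.32-fold. TMEM100 was 12.60 ± 0.44 against 10.32 ± 1.27, and CREB3L4, a transcription factor of the endoplasmic reticulum membrane, 10.06 ± 0.27 against 8.39 ± 0.32. The arrays of these 4 genes did not overlap between the groups, but the genes were picked for a low p, which makes that likely. None passed: limma called 0 probe sets, with a lowest adjusted p of 0.601. At an unadjusted p under 0.05 there were 485, where 838 are expected by chance. Without the 3 arrays that stand apart limma called 0, with 1112 and a lowest adjusted p of 0.203. HEPACAM2 (0.87), DPYS of pyrimidine breakdown (1.21), SRP9 (0.59), TP53BP2 (0.66), the mitochondrial acyl carrier protein NDUFAB1 (0.50) and the mitochondrial citrate carrier SLC25A1 (0.82) were also higher without passing.

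Mitochondrial oxidative phosphorylation genes rose after estrogen at day 13, with 24 of 27 higher by a small median of 0.19 (adjusted p = 6.78e-07; adjusted p = 0.395 with an estimated correlation); 0 passed adjusted over the list alone or over all probe sets. Fry gave p = 0.101, and the exact test of the list score p = 0.114 (Benjamini-Hochberg p = 0.457). In control gilts at day 13 the list scores were -0.26, -0.21 and -0.24 on replicates 1 to 3 and 0.08 on replicate 4, without which the median was 0.28. With RNA quality as a covariate and without the 3 arrays it was 0.10 and the call ended (adjusted p = 0.186). Cholesterol metabolism and smooth muscle genes rose by medians of 0.19 and 0.16, and interferon response and cell cycle genes fell by medians of -0.23 and -0.39, each at an adjusted p of 0.0354 (adjusted p = 0.395, 0.395, 0.615 and 0.615 with an estimated correlation). All 4 calls ended without control day 13 replicate 1 (adjusted p = 0.382, 0.325, 0.646 and 0.789), and the cell cycle median then was 0.00013. Without control day 13 replicate 3 the cholesterol and smooth muscle medians were 0.10 and 0.31, and without control day 13 replicate 4 the cell cycle median was -0.61. The cholesterol median turned to -0.06 without estrogen day 13 replicate 2 (adjusted p = 0.222). Integrins, mucins and junction genes fell by a median of -0.16 with 18 of 25 lower (adjusted p = 0.0446; adjusted p = 0.395 with an estimated correlation); the call ended when any 1 of 8 arrays was left out, with adjusted p up to 0.175. None of these lists had a member past the threshold over all probe sets or adjusted over the list alone. The respiratory chain (median 0.15, adjusted p = 0.0145) and integrin (-0.13, adjusted p = 0.0145) lists stayed called without the 3 arrays that stand apart. Gland secretions (-0.17, 21 of 28 lower, adjusted p = 0.0215), interleukin 1 and cytokines (-0.21, adjusted p = 0.0215) and epithelial markers (-0.18, adjusted p = 0.034) were then called as lower. All 5 were lost with an estimated correlation (adjusted p = 0.208 to 0.876). With all arrays gland secretion genes did not pass as a list (median 0.05, adjusted p = 0.674), and their member CLU, clusterin, chosen after its values were seen, differed by -0.83 ± 0.25 (SE). SPP1, the osteopontin of the attachment surface, was 12.80 ± 1.45 in estrogen and 13.39 ± 1.14 in control gilts, and the prostaglandin list had a median of -0.04 (adjusted p = 0.438).

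At day 15, interferon response and antigen presentation genes were higher in estrogen than in control gilts as a list. This call was lost with an estimated correlation (adjusted p = 0.288). In limma 0 probe sets passed, with 642 at an unadjusted p under 0.05 where 838 are expected by chance. Without the 3 arrays that stand apart 0 passed, with 1394. PIGR, the receptor that carries immunoglobulin A across epithelium, was 9.50 ± 0.60 in estrogen and 8.27 ± 0.37 in control gilts (SD, n = 3 each), or 2.34-fold. COL1A2, a chain of type I collagen, was 8.89 ± 0.37 against 9.74 ± 0.41 on its brightest probe set, and differed by -0.17 on another. SLMAP differed by -0.90 ± 0.24 (SE), and NAPRT, an enzyme of NAD synthesis from nicotinic acid, by 0.67 ± 0.19. YWHAE (0.83), BLOC1S1 (0.52), ARFGAP3 (-0.56, but -0.13 and 0.39 on its other probe sets), the lipid carrier SCP2 (0.99), APOBEC3B (0.81) and SP140 (0.85) completed the lowest p values, none past the threshold.

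The interferon list rose after estrogen at day 15, with 32 of 35 higher and a median of 0.56 (adjusted p = 4.67e-08; adjusted p = 0.288 with an estimated correlation); 0 members passed adjusted over the list alone or over all probe sets. Fry gave p = 0.0496, and the exact test of the list score p = 0.1, the smallest possible here. PSME2, an activator subunit of the immunoproteasome, differed by 0.72 ± 0.25 (SE), IRF7 by 1.03 ± 0.44 and CXCL9 by 2.24 ± 1.07. CXCL9 was 5.04 on control day 15 replicate 3 and 9.89 and 10.14 on the remaining control arrays. The list scores lay close, with 0.46, 0.36 and -0.19 on control and 0.49, 0.56 and 1.23 on estrogen arrays. Without estrogen day 15 replicate 3 the median was 0.26 (adjusted p = 0.00952), and without the 3 arrays that stand apart 0.45 (adjusted p = 1.16e-05; adjusted p = 0.944 with an estimated correlation). Cell cycle genes rose by a median of 0.87 with 19 of 20 higher (adjusted p = 1.88e-05; adjusted p = 0.646 with an estimated correlation), and this ended without estrogen day 15 replicate 2, where the median was 0.27 (adjusted p = 0.563). Cholesterol genes fell by a median of -0.38 with 15 of 21 lower (adjusted p = 0.00488; adjusted p = 0.282 with an estimated correlation), which ended without control day 15 replicate 3 or estrogen day 15 replicate 2 (adjusted p = 0.158 and 0.489). WNT and related genes and stromal fibroblast genes fell by medians of -0.29 and -0.12, both at an adjusted p of 0.0342 (adjusted p = 0.273 with an estimated correlation for each). COL1A2 passed adjusted over the stromal list alone, and 0 members of the cell cycle, cholesterol and WNT lists did. The WNT call ended when any 1 of 3 arrays was left out and the stromal call when any 1 of 4 was, with adjusted p up to 0.263 and 0.156. The WNT median was -0.13 and -0.11 without control day 15 replicate 2 and replicate 3, and the stromal median -0.27 without control day 15 replicate 2. Chaperones (0.26, 18 of 21 higher, adjusted p = 0.0381) and epithelial markers (0.27, 14 of 15 higher, adjusted p = 0.0135) were called as higher without the 3 arrays, and WNT genes (-0.15, adjusted p = 0.0381) still as lower; all 3 were lost with an estimated correlation (adjusted p = 0.973, 0.49 and 0.49).

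Averaged over both days, estrogen and control gilts differed in 0 probe sets in limma (539 at an unadjusted p under 0.05), and in 0 without the 3 arrays that stand apart (1452). HEPACAM2 was 0.77 ± 0.15 (SE) higher after estrogen, with no overlap of groups on either day, SCP2 0.84 ± 0.20, CREB3L4 1.34 ± 0.35 and CCL28, a mucosal chemokine, 1.32 ± 0.38. HNRNPL differed by -2.30 ± 0.60, ARFGAP3 by -0.45 (-0.11 and 0.00 on its other probe sets), WARS by 0.76, ATP6V0D2 by 0.97, MFSD1 by 0.76 and SLCO3A1 by 0.77. Without control day 15 replicate 1, 4 probe sets passed, CCL28 (1.80, adjusted p = 0.00537) and CREB3L4 (1.73, adjusted p = 0.0454) among them. Interferon and respiratory chain genes rose by medians of 0.19 and 0.09 (adjusted p = 0.0178 and 0.034), and collagen and matrix genes, stromal markers and complement genes fell by medians of -0.16, -0.13 and -0.11 (adjusted p = 0.0178, 0.034 and 0.0407). With an estimated correlation these 5 calls were lost (adjusted p = 0.74 for the first pair, and 0.68, 0.327 and 0.68), and each ended when any of at least 4 single arrays was left out. The collagen median was -0.25 without control day 15 replicate 2, -0.10 without estrogen day 15 replicate 1 and -0.25 without estrogen day 15 replicate 2. The complement median was -0.21 without control day 13 replicate 4 and -0.19 without estrogen day 15 replicate 3, and its sign turned without estrogen day 15 replicate 2 (0.03). The collagen scores of the 3 arrays that stand apart were 0.94, 1.02 and 0.75, against -0.22 to 0.13 on the others. Without these 3 arrays the interferon list alone was called (adjusted p = 0.0197), and this call too was lost with an estimated correlation. The collagen, stromal and complement medians were then -0.02, -0.04 and 0.08. None of these lists had a member past the threshold over all probe sets or adjusted over the list alone.

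The last comparison asked whether the estrogen effect differed between the days. In limma 0 probe sets passed for this difference, with 595 at an unadjusted p under 0.05, and 0 without the 3 arrays that stand apart, with 1070. FAM107A had the lowest p, with a difference of -1.46 ± 0.33 (SE): the estrogen effect was 1.22 at day 13 and -0.25 at day 15. PLEK, a protein of platelets and leukocytes, differed by 2.50 ± 0.72, TMEM175 by 1.95 ± 0.56, DPYS by -1.54 ± 0.45 and TSPAN14 by -1.51 ± 0.44. ZFAND2A (-1.15), NAPRT (0.93), SLMAP (-1.14), TSR3 (0.78) and SLC3A1 (-0.88) followed. By list, the estrogen effect on interferon genes was higher at day 15 by a median of 0.71, with 33 of 35 members that way (adjusted p = 2.61e-08), and on cell cycle genes by 1.26 (adjusted p = 2.58e-06). It was lower at day 15 for respiratory chain genes by a median of -0.22 (adjusted p = 1.34e-04), for cholesterol genes by -0.52 (adjusted p = 1.64e-04) and for smooth muscle genes by -0.39 (adjusted p = 0.00631), and higher for epithelial genes by 0.36 (adjusted p = 0.0358). With an estimated correlation all 6 calls were lost (adjusted p = 0.337 to 0.345), and 0 members passed over all probe sets or adjusted over the list alone. The cell cycle, cholesterol and smooth muscle calls also ended without the 3 arrays that stand apart (adjusted p = 0.555, 0.524 and 0.117). Without estrogen day 15 replicate 2 the cell cycle median was 0.61 and the cholesterol median -0.27, the cholesterol median was -0.25 and -0.27 without control day 15 replicate 1 and replicate 3, and without estrogen day 15 replicate 3 the respiratory chain median was -0.13. With RNA quality as a covariate the respiratory chain and epithelial calls ended (medians -0.03 and 0.27, adjusted p = 0.0995 and 0.32). The smooth muscle call ended without control day 13 replicate 2 or control day 15 replicate 1 (adjusted p = 0.0584 and 0.0851), with a median of -0.23 without control day 15 replicate 3, and the epithelial call when any 1 of 9 arrays was left out, with adjusted p up to 0.171. The epithelial median was 0.18 without control day 13 replicate 1.

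Across probe sets, which are not independent replicates, the estrogen effects of the 2 days, measured on separate gilts, correlated at Pearson r = -0.03 and Spearman rho = -0.07, and at 0.16 and 0.09 without the 3 arrays that stand apart. Of probe sets with an unadjusted p under 0.05 on both days, 22 had the same direction where 9.22 were expected by chance and 14 the opposite where 9.37 were expected; without the 3 arrays these were 76 against 45.7 and 31 against 46.8. The differences between the days in control and in estrogen gilts, likewise from separate animals, correlated at r = 0.28 and rho = 0.22. Of probe sets with an unadjusted p under 0.05 in both day comparisons, 107 had the same direction where 28.1 were expected by chance and 8 the opposite direction where 28.4 were expected. A fit of the day effect pooled over treatments, added after the data were seen, called 1 probe set, MRC1 (2.01 ± 0.24 SE, adjusted p = 0.013), with 1434 at an unadjusted p under 0.05. Without the 3 arrays the pooled fit called 165, with 122 higher and 43 lower at day 15.

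Of the 25 gene lists, those not called in any comparison with all 14 arrays had these median differences between the days in control and in estrogen gilts. Gland secretions had 0.16 and 0.11 (28 genes; the mean in estrogen gilts was -0.04), prostaglandin synthesis 0.36 and 0.20 (10 genes), and interleukin 1 and inflammatory cytokines 0.22 and 0.39 (17 genes). Nutrient, ion and water transport had 0.13 and -0.08 (28 genes; the mean in control gilts was -0.07), endoplasmic reticulum chaperones 0.15 and 0.23 (21 genes), and hypoxia and glycolysis genes 0.17 and 0.05 (19 genes). Apoptosis regulators had -0.05 and 0.03 (12 genes), endothelial markers 0.16 and 0.11 (11 genes), and trophoblast markers -0.21 and 0.52 (6 genes; the mean in control gilts was 0.08). The 2 measured red blood cell genes, too few to test, had 0.28 and 0.22.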

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

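The tests of the 3 arrays, of the interferon and macrophage pattern and of a shared day effect were all chosen after the results had been seen; the search for far samples and the tests of the difference between the days were planned. In groups of 4 arrays, 9 of 152 groups had a sample far from the others, where chance gives about 1 in 20 groups, or 7.6 here. Control day 13 replicate 1 accounted for 4 of them. Its gland secretion score was -0.9967, against -0.004298 to 0.1423 in the rest of its group, and its receptor target score -0.1208 against 0.01901 to 0.04299. Its chaperone score was 0.1474 against -0.1127 to -0.07244, and its median correlation with the other arrays 0.8603 against 0.9431 to 0.948. Control day 13 replicate 4 had an oxidative phosphorylation score of 0.08377 against -0.259 to -0.2072 and an NDUFAB1 log2 value of 11.67 against 11.26 to 11.32. Control day 13 replicate 3 had a GAPDH 3' minus 5' difference of 2.59 against 1.994 to 2.092. Estrogen day 13 replicate 1 had an interferon score of -0.1171 against -0.3458 to -0.3099, and estrogen day 13 replicate 2 an SP140 value of 9.278 against 9.191 to 9.203.

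The estrogen effect differed between the days for 6 lists, by the test of the difference itself. The medians were 0.7075 for interferon response, 1.262 for cell cycle, -0.5227 for cholesterol metabolism, -0.2225 for oxidative phosphorylation, 0.3586 for epithelium and -0.3863 for smooth muscle. None passed with an estimated correlation. Without the 3 arrays that stand apart the cell cycle, cholesterol and smooth muscle calls ended (medians 0.07, -0.14 and -0.37, adjusted p = 0.555, 0.524 and 0.117), and with RNA quality as a covariate the oxidative phosphorylation and epithelium calls did (medians -0.03 and 0.27, adjusted p = 0.0995 and 0.32). The interferon call stayed in both.

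The first pattern is the 3 arrays that stand apart. RNA degradation would raise the 3' minus 5' differences of control transcripts, but 0 of 9 lay above the highest of the other 11 arrays, and for GAPDH they were 1.09 on control day 15 replicate 3 and 1.36 on estrogen day 15 replicate 2, under the lowest of the others, 1.86. Scaling was tested by quantile normalization, after which all 3 arrays were still apart, and smooth muscle in the sampled tissue by its list score, which in 0 of the 3 arrays was above the highest of the others. The arrays come from 3 different groups, so the design names no factor that sets them apart. Their collagen and matrix scores were 0.94, 1.02 and 0.75, against -0.22 to 0.13 on the others, and a different share of other tissue, a mislabelled sample, a different stage or another difference in RNA quality stays open.

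The second pattern is that interferon and macrophage genes were higher at day 15 than at day 13 in estrogen gilts. The scaling of the arrays is argued against by an interferon median of 0.8989, the lower under quantile normalization and median centring, and a single array by a lowest median of 0.7346 when each array was left out in turn. The 3' minus 5' differences of actin and EF1A were higher at day 15 by 0.54 and 0.16 (exact p = 0.143 and 0.114). With such differences as a covariate the interferon median was 0.8891 with all arrays, which argues against RNA quality as the whole cause. Among the day 15 arrays, only estrogen day 15 replicate 2 did not lie above the day 13 arrays on these differences. Without the 3 arrays the median was 1.41. That fit cannot part RNA quality from day, because both day 15 arrays left lay above every day 13 array. More leukocytes in the sampled tissue is a candidate explanation that these values cannot decide. Of 22 measured macrophage and lymphocyte genes 20 were higher at day 15, although the neutrophil gene S100A9 differed by 0.18 ± 1.38. The macrophage genes are part of the pattern itself, so only the lymphocyte genes (10 of 11 higher) add to it. Their list call ended without estrogen day 15 replicate 3, and with RNA quality as a covariate over all arrays. Regulation within resident cells was not tested and stays open.

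The third pattern is that macrophage and interferon genes were higher at day 15 in both treatments, which may be a day effect shared by both. In control gilts the macrophage and interferon calls were lost with an estimated correlation (adjusted p = 0.255 and 0.594), and the interferon score of control day 15 replicate 3 was -0.19, under 0.39 and 0.06 on a pair of day 13 arrays. The macrophage score, permuted within treatments, gave an exact p of 0.00245 and a Benjamini-Hochberg p of 0.05878, which misses the threshold. MRC1 passed in the fit pooled over treatments, which called 165 probe sets without the 3 arrays. That fit averages the treatments, as the permuted score does, and can pass when only 1 of them changes. Without the 3 arrays, control gilts alone gave 0 calls and estrogen gilts 221. Other values go with a shared effect but cannot decide it. Of probe sets with an unadjusted p under 0.05 in both treatments, 107 moved the same way where 28.1 were expected. Another 8 moved the opposite way where 28.4 were expected. The expected numbers take probe sets as independent, which they are not. How often chance would give such an excess is therefore not known. A shared day effect therefore stays open.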

How the results depend on the processing

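The alternatives without the 3 arrays that stand apart, with a block in the day 13 groups alone and with RNA quality as a covariate were chosen after the results had been seen; the others were planned. Lists that stayed past the threshold in these alternatives, all at the preset correlation, were, between the days in estrogen gilts, interferon (medians 0.73 to 1.41) and macrophage (0.73 to 1.33); in control gilts, cholesterol (0.28 to 0.78) and oxidative phosphorylation (0.15 to 0.36); after estrogen at day 15, interferon (0.26 to 0.74); and, for the difference between the days, interferon (0.48 to 0.91). All 6 calls were lost with an estimated correlation (adjusted p = 0.136 to 0.337).

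Between the days in estrogen gilts, limma called 0 probe sets with all arrays and 1443 had an unadjusted p under 0.05. It called 3 without the filter on dim probe sets (FCN1, KCNJ1 and an unnamed one, all higher at day 15), 99 with only the groups compared, 168 with array weights, 221 without the 3 arrays, and 0 to 44 when each array was left out; the 44 were without control day 13 replicate 1. The other planned settings gave 0. When each array was left out, the count was 0 to 4 for estrogen against control over both days (4 without control day 15 replicate 1) and 0 to 1 between the days in control gilts (1 without the same array). The cause was not tested.

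With the replicate number as a block in the fit of all groups, limma called 0 probe sets in all 6 comparisons, with 463 to 1142 at an unadjusted p under 0.05, and 3 list calls ended. At day 13, where the numbers were treated from the values alone as possible pairs, the block in the day 13 groups alone gave 0. It had 800 at an unadjusted p under 0.05 and changed no list call.

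With RNA quality as a covariate, limma called 0 probe sets in all 6 comparisons with all arrays, with 551 to 2743 at an unadjusted p under 0.05, and 0 without the 3 arrays, with 603 to 1174. With all arrays 9 list calls ended. These were interferon at day 13 (adjusted p = 0.11), stromal at day 15 (0.137), and interferon, collagen and stromal over both days (0.2, 0.2 and 0.0662). The others were ciliated epithelium in control gilts (0.0642), lymphocyte in estrogen gilts, and oxidative phosphorylation and epithelium for the difference. Without the 3 arrays 9 of the calls made with all arrays ended and 6 reversed. Oxidative phosphorylation at day 13 was then 0.10 and no longer passed (adjusted p = 0.186). The cause was not tested.

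Directions reversed in few results. The cell cycle median at day 13 was 0.0001319 without the 3 arrays and -0.612 to 0.0001319 when each array was left out. The cholesterol median at day 13 was -0.05698 to 0.2849 when each was left out, lowest without estrogen day 13 replicate 2. The complement median over both days was 0.08295 without the 3 arrays and -0.2096 to 0.02664 when each was left out, highest without estrogen day 15 replicate 2. SLC34A2 between the days in estrogen gilts was -1.476 to 0.5917 when each was left out, highest without estrogen day 15 replicate 3, and 0.6215 with RNA quality as a covariate. With that covariate and without the 3 arrays, the cell cycle median was 0.004713 at day 13, -0.04338 at day 15 and -0.09712 for the difference between the days. The cholesterol median at day 15 was then 0.121, the complement median over both days 0.08773 and the oxidative phosphorylation median for the difference 0.1913. The cause was not tested.

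With planned or added alternatives other than leaving out 1 array, 926 gene results stayed uncalled, as with all arrays, 73 newly passed and 1 reversed; 396 list results kept their call, 80 no longer passed and 8 reversed. When 1 array was left out, 1086 gene results stayed uncalled, 18 newly passed and 2 reversed; 392 list results kept their call, 95 no longer passed and 3 reversed.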

Other observations

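All tests of other splits were chosen after the results had been seen, that without the 3 arrays that stand apart included. With all arrays the real groups gave 0 probe sets in limma in each comparison, so every split gave at least as many and these counts say nothing about chance. The splits numbered 35 at day 13 (highest other 1), 35 between the days in control gilts (highest other 9), 35 between the days in estrogen gilts (highest other 2), and 100 each for both days together and for the difference between the days (highest others 3 and 2). Counts at an unadjusted p under 0.05 can differ between splits: 16 of 35 gave as many as the real 485 at day 13, 27 of 35 as many as 656 in control gilts, and 2 of 35 as many as 1443 in estrogen gilts. For both days together 68 of 100 gave as many as 539, and for the difference between the days 66 of 100 as many as 595. By these counts chance cannot be excluded in the 5 comparisons. At day 15 the 10 splits are too few for a share under 0.05; the real value was 0 and the highest other 1, and 7 of 10 gave as many as the real 642 at an unadjusted p under 0.05. Other splits had up to 3207 in control gilts, 2924 at day 15, 2908 for both days together and 3084 for the difference. This points to a structure of the samples other than the groups compared. Each of these comparisons holds more than 1 of the 3 arrays that stand apart. The comparisons with only 1 of them reached 1019 at day 13 and 1518 between the days in estrogen gilts. Without the 3 arrays, the 15 splits between the days in estrogen gilts are too few as well; the real value was 221, the highest other 2, and 1 split, the real one, gave as many. At day 13 the 8 splits that part every same-numbered pair are also too few: with the block in the day 13 groups alone the real value was 0, with 800 at an unadjusted p under 0.05, and the highest others were 0 and 1005.

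Single arrays had values outside the range of the others for these genes. On control day 13 replicate 1, ACP5, the uteroferrin of gland secretions, was 11.40, against 13.86 to 15.20 on the other arrays. On control day 15 replicate 3, LIF was 11.71 and PTGS2 12.02. On estrogen day 15 replicate 2, TOP2A was 10.62 and CCNB1 10.82.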
